A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

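Leaves of drought-treated rice seedlings of 2 genotypes were profiled by paired-end RNA-seq with reads of 150 nt, per the labels' protocols, with 2 libraries per genotype. Groups and replicate numbers came from the sample titles, and each FPKM column was matched to its sample by the library name in the labels. Nothing in the labels says that the libraries of a genotype came from separate plants or pools, so p-values measure the spread between these libraries, which may be technical. Sample labels give the molecule as genomic DNA, while the protocol describes RNA, and the values were treated as RNA-seq.

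The authors deposited one FPKM value per gene and library, per the file headers, on rice gene identifiers of the RAP type with coordinates, names and descriptions. What computed the FPKM is not given in the sources used here. The submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.0, DESeq2 1.38.3 and the build IRGSP 1.0, with no role or order. Coordinates are those of the deposited table, taken to be on that build. The authors also deposited 2 lists with a log2 fold change, a p-value, an adjusted p-value and a linear fold change per gene, per the file headers, on identifiers of the MSU type. The header of one list stands 1 column away from its values, and its columns were read by position. Of the genes marked up, 1135 carried exactly 1 RAP identifier beside the MSU identifier, and these were paired with the FPKM table. The list marked down carries no RAP identifier, and its genes are not named here. The adjusted p-value is blank for 72 and 33 genes, and 1 linear fold change differs from its log2 value by more than 0.01 on the log2 scale. A further sheet repeats 1 gene with 9 unlabelled value columns. The first 4 equal that gene's FPKM in the 4 libraries, and the others match no sample. A further 2 unlabelled columns hold 4 stray cells. None of these were used. Gene names came from the deposited table.

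The test planned for counts could not be used, since no counts were among the files. The fallback fixed before the data were examined was used: limma 3.58.1 in R 4.3.3, with trended variance, on log2(FPKM + 1), over the 20174 genes with a mean FPKM of at least 1. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. No whole-read steps were seen in low FPKM values, so read depth is unknown, and no counting interval is given. With 2 libraries per group the residual degrees of freedom were 2 and the fitted prior added 3.30. An exact permutation test of a single value could not go below 0.333 in this design.

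The steps were tested on simulated data for this comparison, with 200 of 20174 genes changed and spreads drawn from the fitted prior. The changed genes, and the simulated lists below, were drawn only from genes averaging about 5 FPKM or more. Recovery of lower genes was not tested. The test recovered 0% of 67 genes with a simulated log2 fold change of 1, 56.7% of 67 with 2 and 97.0% of 66 with 4, with 6 false calls. A list of 40 genes shifted by 0.5 was found by the set test, and an unshifted one was not. The simulated genes varied independently of each other. In the real lists that passed, the estimated correlation between genes ran from -0.06 (TIFY/JAZ) to 0.66 (photosystem subunits). How often lists of correlated genes pass without a shift was therefore not tested.

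Fixed lists of genes, 37 in all, were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 31 lists with at least 5 tested members. Of the lists, 7 were given by identifier and 30 by words in the gene description. Of 122 identifiers, 8 were dropped because name or description did not match and 3 were not found. Set tests were repeated with an estimated correlation and with fry. None of the 31 lists passed with an estimated correlation (lowest adjusted p 0.732) or with the directional test of fry (lowest adjusted p 0.124). With an estimated correlation camera also rests on the 2 residual degrees of freedom, so a list could hardly pass. For amino acid transporters the estimate, -0.007, lay below the preset 0.01, yet camera's unadjusted p rose from 0.00011 to 0.048. Heat shock (-0.012) and TIFY/JAZ (-0.06) also lay below it, and the other passing lists above it. These failures cannot tell correlation between genes from the small design. Fry's mixed test asks whether genes of a list change in either direction. With this mixed test 12 lists passed, among them nitrogen use (adjusted p = 0.0337), pathogenesis-related proteins (0.000432) and the cytosolic ribosome (0.0322). The pathogenesis-related list was made by words in the description. It also holds the transcription factor gene OsERF_047, whose value is uncertain, as described below. The median, the mean and the set test differed in sign for 3 of the 31 lists: cytochrome P450s, seed storage proteins and NLR immune receptors.

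Genes were named by a rule fixed at the same time: OsWOX13; up to 6 called genes in each direction with the largest fold changes, a mean FPKM of at least 5, groups that do not overlap and a named product; called members of the lists; and, for the drought and nitrogen lists, the members with the smallest p up to 3. The minimum of 5 was written for CPM and was read as FPKM. Other genes are said in the text to have been chosen after their values were seen. Genes covered by at least 50% by a gene on the other strand were counted, since the deposited values may divide reads between such genes. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean of at least 5), a replicate block, stricter thresholds, each library left out, and, added after the data were seen, median-of-ratios scaling, quantile normalisation and leaving out overlapped genes.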

Results

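RNA-seq was run on leaves of rice seedlings (Oryza sativa, Japonica group) that were 14 days old and had been under drought for 6 h. OsWOX13 is a WUSCHEL-related homeobox transcription factor, and the series' title names its acetylation, drought-responsive genes and nitrogen use. The labels give 2 genotypes with 2 libraries each. OE13 is labelled drought resistant and OE13-2KR/oswox13-1 drought sensitive. There was no wild-type group and no watered group, so each value describes one drought-treated line against the other. By its name, OE13-2KR/oswox13-1 differs from OE13 in both the 2KR form and the oswox13-1 background, which cannot be told apart here. No difference below can therefore be assigned to acetylation of OsWOX13. The deposited table held FPKM (fragment counts scaled to gene length and library total) for 33744 genes, and FPKM summed to between 931335 and 941593 per library. The number of reads behind each library is unknown. Between 3973 and 4819 genes were listed at 0 per library, most in OE13-2KR/oswox13-1 replicate 2. The chloroplast genome held 0.0348% and 0.0350% of summed FPKM in OE13-2KR/oswox13-1 replicates 1 and 2, and 0.0439% and 0.0422% in those of OE13. The rRNA genes held 0.104% and 0.0917% against 0.138% and 0.113%. Both shares separated the lines without overlap, which 2 against 2 libraries do by chance in 0.333 of cases.

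OsWOX13 itself was checked first, since both lines were made around it. The locus (Os01g0818400, chromosome 1, 34863111 to 34865653, plus strand) is listed in the deposited table under the name OsWOX8. That it is OsWOX13 was taken from general knowledge of the locus and could not be checked in the files, so the values below are OsWOX13's only if this holds. Its FPKM was 27.1 and 49.9 in the OE13-2KR/oswox13-1 libraries and 22.02 and 75.6 in the OE13 libraries. The group means were 38.5 ± 16.2 and 48.8 ± 37.9 (SD, n = 2 each). The log2 fold change was -0.15 (SE 0.62, limma adjusted p = 0.907), and the groups overlapped. Its direction turned with the libraries used: it was 0.28 without OE13-2KR/oswox13-1 replicate 1 and 0.72 without OE13 replicate 2. FPKM per gene does not separate a transgene from the resident copy.

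The main comparison asked which transcripts differed between the 2 lines under drought. The first principal component ordered the libraries by genotype. It carried 63.7% of the variance, with scores of -63.0 and -18.1 for OE13-2KR/oswox13-1 and 30.0 and 51.2 for OE13. Across genes, which are not independent replicates, OE13-2KR/oswox13-1 replicate 1 correlated about as closely with OE13 replicate 1 (r = 0.962) as with replicate 2 of its own line (r = 0.967). In single-gene tests 1 of 20174 genes passed the threshold. This was OsERF_047, an AP2/ERF-type transcription factor gene, listed at 0 in both OE13-2KR/oswox13-1 libraries and at 41.9 and 34.7 FPKM in the OE13 libraries (limma, adjusted p = 0.0247). At an unadjusted p under 0.05, 1613 genes were higher and 2415 lower in OE13-2KR/oswox13-1, which is 19.97% of the genes tested. That split was not stable to scaling: 40.04% of these genes were higher as deposited and 52.1% after the libraries were rescaled by their median ratio, giving 2090 higher and 1921 lower. Quantile normalisation gave 52.3% and moved the median log2 fold change of all genes from -0.08 to 0.03. With 1 library left out the numbers lay between 783 and 1580 higher and between 1000 and 3382 lower. The lowest numbers were without OE13 replicate 2 and the highest without OE13-2KR/oswox13-1 replicate 1.

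OsERF_047 (Os03g0191900, chromosome 3, 4780248 to 4781570, minus strand) lies wholly within the span of Os03g0191850, a hypothetical gene on the plus strand from 4780247 to 4781570. The plus-strand gene ran the other way, at 28.1 and 27.9 FPKM in OE13-2KR/oswox13-1 and 12.7 and 10.6 in OE13 (log2 fold change 1.20, SE 0.19, limma adjusted p = 0.187). Reads from such a pair cannot be told apart without strand, and no stranded counting is given in the sources used here, so the value of OsERF_047 is uncertain. Summed over the pair, FPKM was 28.1 and 27.9 in OE13-2KR/oswox13-1 and 54.6 and 45.3 in OE13. Such a sum is no read total over the span, since FPKM is scaled to each gene's own length. The call of OsERF_047 ended when any 1 of the 4 libraries was left out, although no single library sets its values of 0 and of 34.7 or more. The call also ended with a replicate block (limma, adjusted p = 0.282) and without a filter on low values (limma, adjusted p = 0.313).

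**Figure D1:**
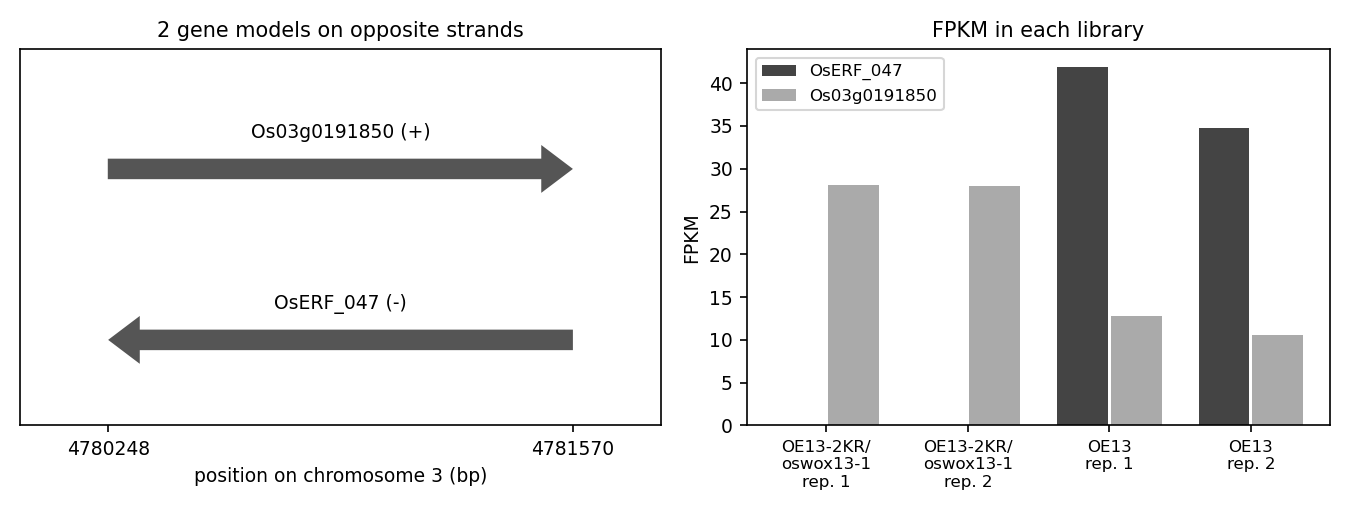
Left, the spans of OsERF_047 and Os03g0191850 on chromosome 3 (bp), with arrows in the direction of transcription. Right, FPKM of both genes in each of the 4 libraries: OsERF_047 is listed at 0 in both OE13-2KR/oswox13-1 libraries and at 41.9 and 34.7 in OE13, and Os03g0191850 is at 28.1 and 27.9 against 12.7 and 10.6.

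The fixed list of drought and abscisic acid (ABA) genes tended to be higher in OE13-2KR/oswox13-1, the line labelled drought sensitive, while broader gene ontology terms did not pass the set test. Of 46 members tested, 32 had a positive and 14 a negative log2 fold change, with a median of 0.13 against -0.08 for all genes. The 3 members with the smallest p were LEA3, a late embryogenesis abundant protein that accumulates under water deficit (Os05g0542500, 146 ± 42.8 against 63.6 ± 12.2 FPKM), the NAC transcription factor gene OsNAC10 (Os11g0126900, 142 ± 56.6 against 57.7 ± 6.57) and DREB1A (Os09g0522200, 17.5 ± 3.38 against 10.2 ± 0.813; SD, n = 2 per group throughout). Their log2 fold changes were 1.17, 1.23 and 0.71, and that of OsNAC10 was 0.81 without OE13-2KR/oswox13-1 replicate 2. None passed singly, with adjusted p of 0.194, 0.194 and 0.209 (limma), and 0 members passed when adjusted over the list alone. At an unadjusted p under 0.05, 6 members were higher and 1, the ABA-degrading enzyme gene ABA8ox2, was lower. ABA8ox2 is covered to 82.6% by a gene on the other strand. The list passed the set test (camera, adjusted p = 0.0169), but not with an estimated correlation (adjusted p = 0.897). It rested on 1 library: without OE13-2KR/oswox13-1 replicate 2 the median was -0.02 and the adjusted p 0.789. The median was 0.40 without replicate 1 of that line and 0.08 without OE13 replicate 2. The list also lost its call without a filter on low values (adjusted p = 0.0663), with a mean FPKM of at least 5 (0.0917) and with quantile normalisation (0.122). Gene ontology terms, looked up after the values were seen and adjusted over 759 terms, did not pass (camera). Response to water deprivation had a median of -0.0025 over 75 genes, with 10 higher and 11 lower at an unadjusted p under 0.05 (adjusted p = 0.334; adjusted p = 0.877 with an estimated correlation). Response to abscisic acid had -0.08 over 77, with 13 higher and 3 lower (adjusted p = 0.476; adjusted p = 0.834 with an estimated correlation). The ABA-activated signaling pathway had 0.02 over 75, with 9 higher and 6 lower (adjusted p = 0.472; adjusted p = 0.903 with an estimated correlation).

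Nitrogen-use genes went both ways. Of 23 tested members, 8 had a positive and 15 a negative log2 fold change, with a median of -0.17, and the list did not pass the set test (camera, adjusted p = 0.867). AlaAT1, an alanine aminotransferase gene (Os10g0390500), stood at 38.2 ± 5.55 FPKM in OE13-2KR/oswox13-1 and 18.9 ± 0.228 in OE13 (log2 fold change 0.97, SE 0.19). TCP19, a transcription factor gene tied to tillering under nitrogen supply (Os06g0226700), stood at 4.44 ± 0.828 and 16.2 ± 6.74 (-1.61, SE 0.33). DEP1, a G-protein gamma subunit gene (Os09g0441900), stood at 5.05 ± 0.412 and 9.83 ± 0.593 (-0.84, SE 0.20). Adjusted over all genes these 3 had p of 0.187, 0.187 and 0.194 (limma). Adjusted over the list alone, 1 member was higher (AlaAT1) and 4 were lower: TCP19, DEP1, the nitrate transporter gene NRT1.1B and the nitrite reductase gene NiR. The last pair, chosen after its values were seen, stood at 149 ± 52.8 against 310 ± 0.189 FPKM for NRT1.1B and 29.7 ± 8.97 against 59.3 ± 6.71 for NiR. The log2 fold change of NRT1.1B, -1.10, was -0.73 without OE13-2KR/oswox13-1 replicate 2. A gene on the other strand covers 93.5% of NiR.

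**Figure D2:**
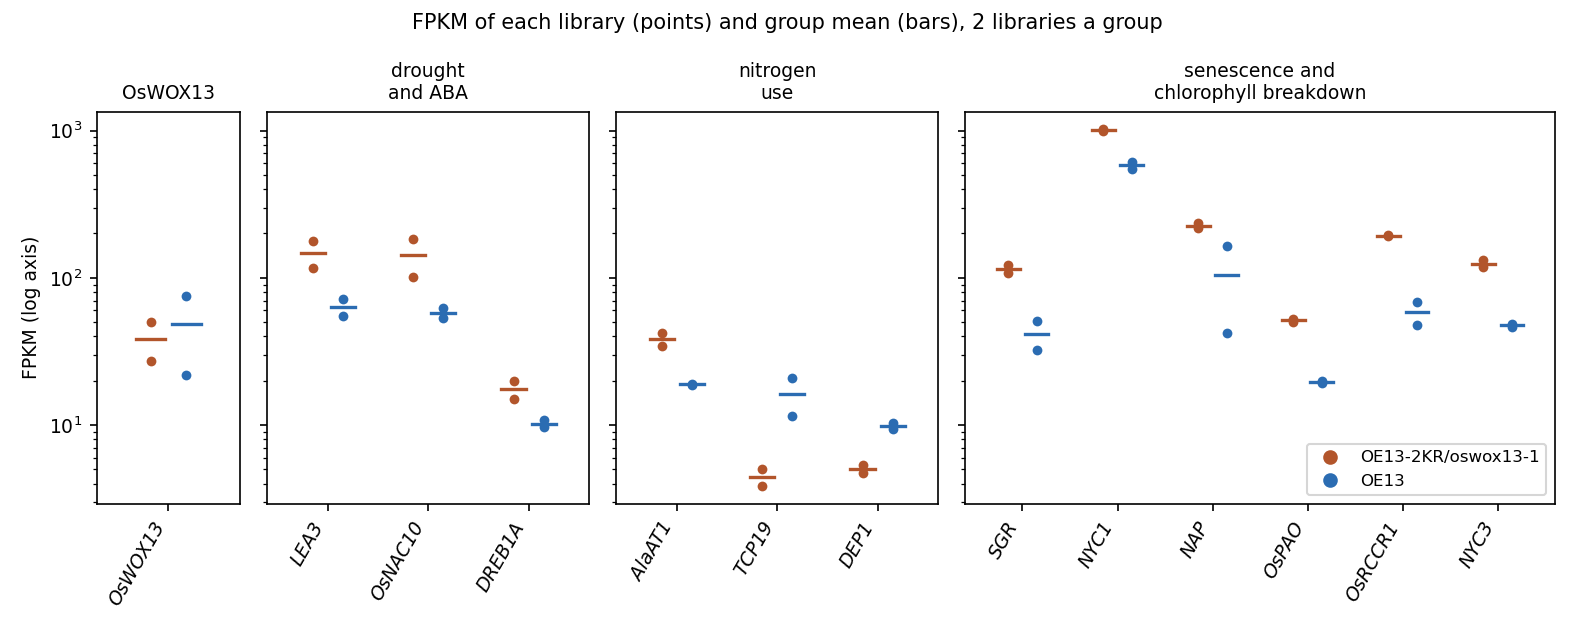
FPKM on a log axis for OsWOX13, 3 drought and ABA genes, 3 nitrogen-use genes and 6 genes of leaf senescence and chlorophyll breakdown; points are the 2 libraries of each genotype and bars their mean. The 2 genotypes overlap for OsWOX13 and do not overlap for the other genes shown, as they do not for 56.2% of all 20174 genes tested.

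The cell wall was covered by the cellulose synthase and expansin lists. In the cellulose synthase family 15 of 20 tested members had a negative log2 fold change, with a median of -0.77 (camera, adjusted p = 0.010; adjusted p = 0.897 with an estimated correlation). Adjusted over the list alone, 10 members were lower and 2 higher in OE13-2KR/oswox13-1; over all genes 0 passed. Among the lower were genes of the primary wall synthase, OsCesA1 (Os05g0176100) at 48.0 ± 17.4 against 111 ± 1.79 FPKM and OsCesA8 (Os07g0208500) at 63.0 ± 40.5 against 222 ± 15.95. The secondary wall genes OsCesA4 (Os01g0750300), CESA7 (Os10g0467800) and BC6 (Os09g0422500) also belonged to them. OsCesA4 stood at 5.19 and 0.420 FPKM in the OE13-2KR/oswox13-1 libraries and at 15.5 and 28.7 in OE13. Without OE13-2KR/oswox13-1 replicate 2 the log2 fold changes were -1.26 for OsCesA8, -1.84 for OsCesA4, -2.29 for BC6 and -1.68 for CESA7, against -1.96, -2.90, -3.48 and -2.72 with all libraries. CESA7 and BC6 are covered to 99.8% and 87.7% by genes on the other strand. The 2 higher members were the cellulose synthase-like genes OsCslE1 and OsCslH1, with log2 fold changes of 0.80 and 0.60; a gene on the other strand covers OsCslE1 in full. Without a filter on low values the median was -0.24 and the list no longer passed (adjusted p = 0.172). These members were named after their values were seen. So was the gene ontology term of secondary cell wall biogenesis, 38 genes of which 3 are in the list, with a median of -0.53 and 1 higher and 16 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.0129; adjusted p = 0.827 with an estimated correlation). Xylan biosynthesis, with -0.23 over 18 genes, did not pass (adjusted p = 0.581; adjusted p = 0.862 with an estimated correlation).

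Cytosolic ribosomal protein genes and photosystem subunit genes were the other lists lower in OE13-2KR/oswox13-1 by the set test. Of 148 cytosolic ribosomal protein genes, 141 had a negative log2 fold change, with a median of -0.44 (camera, adjusted p = 3.4e-12; adjusted p = 0.732 with an estimated correlation). At an unadjusted p under 0.05, 61 were lower and 0 higher, and 0 passed limma's test adjusted over all genes or adjusted over the list alone. Examples chosen after the values were seen are genes for the 60S proteins L17 (Os10g0466700, 58.9 ± 10.7 against 135 ± 19.4 FPKM) and L31 (Os08g0505300, 8.56 ± 0.878 against 19.0 ± 1.39). Of 27 photosystem subunit genes, 24 had a negative log2 fold change, with a median of -0.69 (camera, adjusted p = 0.0160; adjusted p = 0.911 with an estimated correlation). Light-harvesting and Calvin cycle genes did not pass (adjusted p = 0.243 and 0.964). The libraries of the 2 lines overlapped for the photosystem list, with a within-group difference of up to 127% of the group difference: the list's median deviation was 0.11 in OE13-2KR/oswox13-1 replicate 1 and 0.00 in OE13 replicate 2. Without OE13-2KR/oswox13-1 replicate 2 the median was -0.26 (adjusted p = 0.313), and without OE13 replicate 1 it was -0.27 (adjusted p = 0.670). It was -1.19 without OE13-2KR/oswox13-1 replicate 1 and -1.15 without OE13 replicate 2. The photosystem call was also lost without a filter on low values (median -0.60, adjusted p = 0.0807) and without overlapped genes (adjusted p = 0.0699). The member with the smallest p, OsPsbR2 (Os07g0147550), ran against the list at 18.4 ± 3.18 against 7.32 ± 0.635 FPKM.

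A further 7 lists were higher in OE13-2KR/oswox13-1 by the set test. Amino acid transporters had a median of 0.29 over 30 genes (camera, adjusted p = 0.00172; adjusted p = 0.732 with an estimated correlation), and adjusted over the list alone 3 were higher, among them OsATL6 (Os02g0191300, 451 ± 28.05 against 208 ± 7.53 FPKM) and OsHT (Os08g0127100, 166 ± 21.6 against 82.1 ± 4.21). Heat shock proteins had a median of 0.08 over 84 genes (adjusted p = 0.010; adjusted p = 0.732 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower. OsHSP82A, a 90 kDa-type chaperone gene (Os08g0500700), stood at 557 ± 46.0 against 200 ± 7.13 FPKM and OsHsp71.1 (Os03g0276500) at 300.1 ± 29.0 against 119 ± 21.5. WRKY transcription factors had a median of 0.14 over 61 genes (adjusted p = 0.010; adjusted p = 0.732 with an estimated correlation), with OsWRKY97 (Os12g0116400) at 18.8 ± 0.523 against 6.92 ± 0.260 and the repressor gene WRKY76 (Os09g0417600) at 6.85 ± 0.821 against 1.91 ± 0.429. The NAC transcription factors picked by words in the description had a median of 0.54 over 15 genes (adjusted p = 0.010, and 0.732 with an estimated correlation). Among them OsY37 (Os06g0675600) stood at 26.5 ± 8.33 against 11.9 ± 0.0990 FPKM. The list does not hold every NAC gene. Outside it, ONAC007 (Os06g0131700), described as similar to NAM protein, ran the other way, with a log2 fold change of -1.28. The authors' deposited table marks ONAC007 up, which means higher in OE13 (adjusted p = 0.00670). Phosphate nutrition genes had a median of 0.17 over 27 (adjusted p = 0.010; adjusted p = 0.732 with an estimated correlation), with the purple acid phosphatase gene OsPAP3c (Os03g0238600) at 54.3 ± 9.93 against 23.7 ± 0.331. Aquaporins had a median of 0.47 over 7 genes (adjusted p = 0.0219, and 0.732 with an estimated correlation). Of these 1, the gene described as aquaporin NIP1-3 (Os05g0205050), passed adjusted over the list alone. The broader gene ontology term water channel activity, looked up afterwards, did not pass (camera, adjusted p = 0.702, and 0.944 with an estimated correlation). Its median was 0.15 over 15 genes, with 1 higher and 3 lower at an unadjusted p under 0.05. The TIFY/JAZ repressors of jasmonate signalling had a median of 0.28 over 11 genes (adjusted p = 0.0357; adjusted p = 0.732 with an estimated correlation), with OsJAZ5 (Os03g0402800) at 482 ± 4.52 against 292 ± 12.3. Medians moved with single libraries. The aquaporin median was 0.11 without OE13-2KR/oswox13-1 replicate 2, 0.22 without OE13 replicate 2 and 0.83 without OE13-2KR/oswox13-1 replicate 1. Without OE13-2KR/oswox13-1 replicate 2 the NAC median was 0.25 and the phosphate median 0.32, and without replicate 1 of that line the amino acid transporter median was 0.46 and the heat shock median 0.12. The heat shock median was 0.03 without OE13 replicate 1 and 0.13 without OE13 replicate 2. Without a filter on low values the medians were 0.037 for amino acid transporters, 0.07 for WRKY, 0.17 for NAC, 0.05 for TIFY/JAZ, 0.03 for phosphate and 0.03 for heat shock genes, and the last 4 of these lists no longer passed. With a mean FPKM of at least 5 the calls of NAC (adjusted p = 0.0917), TIFY/JAZ (0.0917) and the aquaporins (0.0654) were lost. Quantile normalisation ended those of TIFY/JAZ (0.106) and the aquaporins (0.0886), and leaving out overlapped genes those of heat shock (0.0699) and the aquaporins (0.0711). Single libraries also ended some of these calls. Without OE13 replicate 1 the WRKY list had an adjusted p of 0.125, NAC 0.0776 and TIFY/JAZ 0.0842. Without OE13 replicate 2 the aquaporins had 0.146 and TIFY/JAZ 0.0836. Without OE13-2KR/oswox13-1 replicate 1 the phosphate list had 0.0594 and TIFY/JAZ 0.0733, and without replicate 2 of that line NAC had 0.0803, the aquaporins 0.198 and TIFY/JAZ 0.0636. Each of the genes named here was chosen after its values were seen, and none passed limma's test adjusted over all genes.

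**Figure D3:**
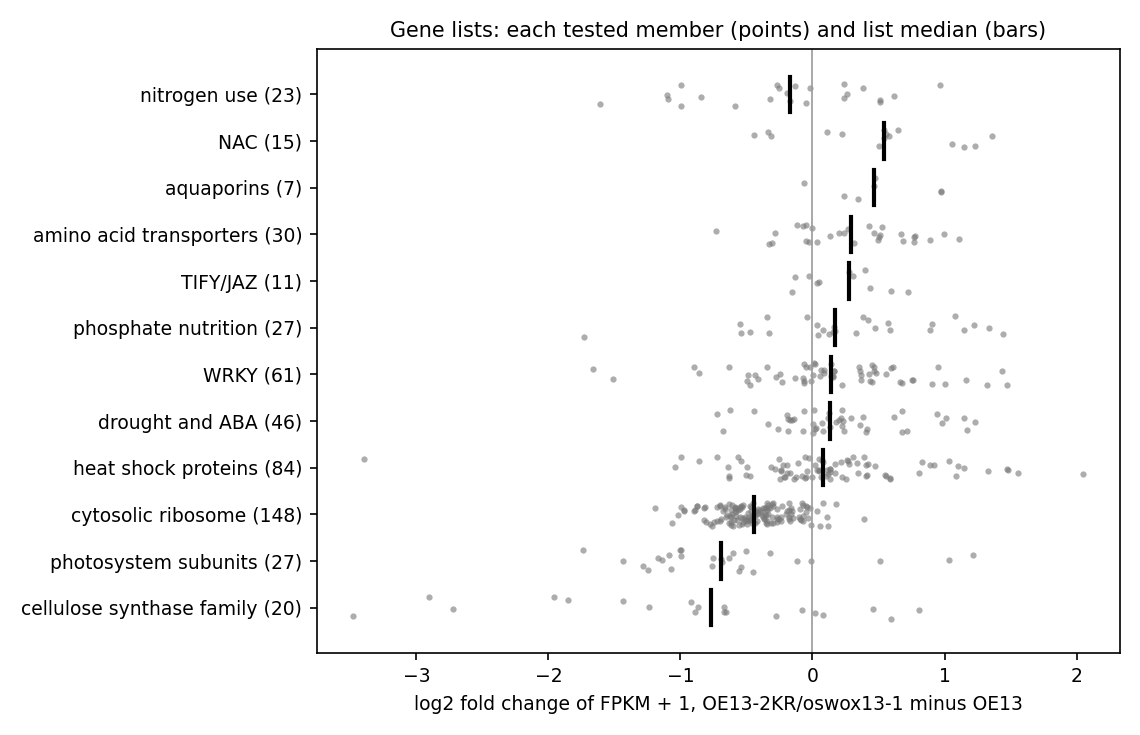
Log2 fold change of FPKM + 1 (OE13-2KR/oswox13-1 minus OE13) for each tested member, as points, and the list median, as a bar, in the 11 lists past the set test and the nitrogen-use list; the number of tested genes stands in brackets. The cellulose synthase family has a median of -0.77 and the NAC list one of 0.54.

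The other 20 lists tested did not pass, with camera adjusted p between 0.147 and 0.998. They were nitrogen use, cytochrome P450s, glutathione S-transferases, class III peroxidases, light-harvesting proteins, LEA proteins and dehydrins, trehalose metabolism, acetylation machinery, expansins, diterpenoid phytoalexin enzymes, cell division, the circadian clock, auxin response, core histones, receptor-like kinases, pathogenesis-related proteins, seed storage proteins, Calvin cycle enzymes, AP2/ERF factors and NLR immune receptors. By the words of its description OsERF_047 fell in the pathogenesis-related list and not in the AP2/ERF list, so neither list covers exactly its family. Of the 10 clock genes 1 had an unadjusted p under 0.05: TOC1, at 51.6 ± 5.73 against 83.4 ± 15.4 FPKM. The 7 tested genes of the acetylation machinery had a median log2 fold change of 0.07. A further 6 lists had too few tested members. Senescence had 3, root markers 1 (Lsi1, log2 fold change 0.24, between 0.09 and 0.38 with 1 library left out), nitrate and peptide transporters 2 (median 0.23) and SWEET sugar transporters 1 (0.82), while meristem markers and organelle-encoded genes had 0.

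The 3 senescence genes each had higher mean FPKM in OE13-2KR/oswox13-1. The chlorophyll-degrading gene SGR (Os09g0532000) stood at 116 ± 9.88 against 41.5 ± 13.1 FPKM, the chlorophyll b reductase gene NYC1 (Os01g0227100) at 1003 ± 23.1 against 581 ± 41.8, and the NAC factor gene NAP (Os03g0327800) at 226 ± 10.6 against 104 ± 87.2. Adjusted over the list alone, SGR and NYC1 were higher. The log2 fold change of NAP, 1.42, was 0.45 without OE13 replicate 1 and 2.39 without OE13 replicate 2. Over all genes their adjusted p were 0.187, 0.194 and 0.280 (limma). Further genes of chlorophyll breakdown, looked up after the values were seen, were OsPAO (Os03g0146400, 51.4 ± 1.59 against 19.7 ± 0.449), OsRCCR1 (Os10g0389200, 194 ± 3.24 against 58.2 ± 14.8) and NYC3 (Os06g0354700, 125 ± 9.74 against 47.5 ± 1.34), each with an adjusted p of 0.187. The gene ontology term leaf senescence, also looked up afterwards, did not pass over 20 genes (median 0.12, 3 higher and 1 lower at an unadjusted p under 0.05; camera, adjusted p = 0.103; adjusted p = 0.827 with an estimated correlation).

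The authors' deposited table holds 2 lists of genes, 1207 marked up and 602 marked down, each with p under 0.05. An adjusted p under 0.05 is given there for 72 of the genes marked up and 8 of those marked down, per the authors' deposited table. Among the genes marked up that could be paired with a gene tested here, 929 had a negative and 2 a positive log2 fold change, OE13-2KR/oswox13-1 minus OE13, so up in the authors' deposited table means higher in OE13. Of the paired genes 785 had an unadjusted p under 0.05 in that direction here, and 0 had an adjusted p under 0.05 (limma). OsERF_047 was not among the paired genes. The authors' lists were deposited for these same 2 genotypes in this series, so their agreement with the FPKM fit is no independent support.

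A few genes with an adjusted p under 0.05 in the authors' deposited table were chosen after their values were seen, and no test was made of what such genes share. The authors' deposited table gives log2 fold changes of 1.98 for the subtilisin-like protease gene OsSub47 (adjusted p = 6.4e-06), 2.15 for the fasciclin-like gene OsFLA6 (0.000266) and 1.098 for the cellulase gene OsGH9B5 (0.000266). The beta-tubulin genes OsTUB1, TUB8 and TUB6 have 1.382, 1.91 and 1.44 in the authors' deposited table, with adjusted p of 0.000911, 0.00787 and 0.0209; genes on the other strand cover 71.8%, 63.9% and 77.3% of them. The xyloglucan endotransglycosylase gene OsXTH17 has 1.90, the mixed-linkage glucan synthase gene CSLF6 has 1.14 and OsCesA1 has 1.16, also from the authors' deposited table. The FPKM fit gave these genes log2 fold changes, OE13-2KR/oswox13-1 minus OE13, of -1.63 (OsSub47), -2.07 (OsFLA6), -1.16 (OsGH9B5), -1.62 (OsTUB1), -2.07 (TUB8), -1.73 (TUB6), -2.57 (OsXTH17), -1.46 (CSLF6) and -1.24 (OsCesA1). RD22, a name for dehydration-responsive genes, stands for a pair of tested loci that ran in opposite directions. Os01g0733500 has 1.72 in the authors' deposited table (adjusted p = 0.00498) and stood at 15.7 ± 8.16 against 69.3 ± 25.01 FPKM. The RD22 locus Os10g0409400 stood at 598 ± 163 against 253 ± 49.4 FPKM, a log2 fold change of 1.22. Of the drought and nitrogen lists, the authors' deposited table marks DREB1C, TCP19 and NRT1.1B up, with adjusted p of 0.474, 0.247 and 0.631. Of the 20 tested cellulose synthase family genes, 9 are marked up in the authors' deposited table, 1 of them with an adjusted p under 0.05, and of the 12 tested expansins 1 is marked up.

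**Figure D4:**
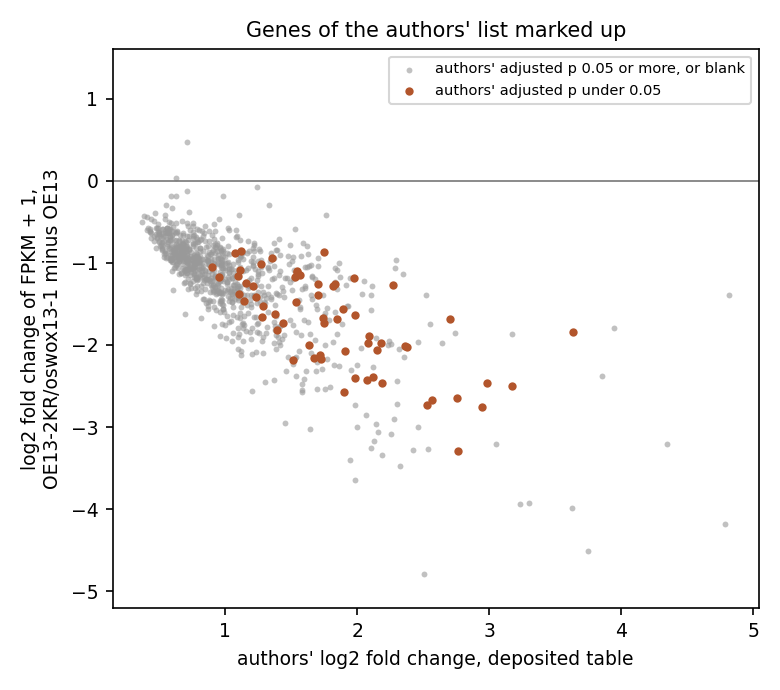
For the paired genes marked up, the log2 fold change in the authors' deposited table (x axis) and the log2 fold change of FPKM + 1, OE13-2KR/oswox13-1 minus OE13 (y axis); coloured points have an adjusted p under 0.05 in the authors' deposited table. On the y axis 929 genes lie below 0 and 2 above.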

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

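Median-of-ratios scaling, quantile normalisation and leaving out overlapped genes were chosen after seeing the data. So were all settings for the numbers at an unadjusted p and for genes chosen after their values were seen, and for the gene lists both pseudocounts and the mean FPKM of at least 5; the other settings were fixed before. The count of differing genes, 1 by the limma test, was 2 with a pseudocount of 5, where the hypothetical gene Os06g0567950 joined OsERF_047. It was 0 without a filter on low values, 0 at an adjusted p under 0.01, 0 with a replicate block and 0 without overlapped genes, a set that leaves out OsERF_047 by construction. It stayed at 1 with a pseudocount of 0.1, a mean FPKM of at least 5 and both scalings. With each library left out in turn, where the lone library of a group is assumed to vary like the others, it ranged from 0 to 5. The 5 genes, each without OE13 replicate 1, were Os01g0606400, Os03g0299700, Os04g0397800, OsSTA185 and Os07g0153150, which were high in OE13 replicate 2 alone. The number at an unadjusted p under 0.05 ranged from 783 to 1580 higher and from 1000 to 3382 lower over the left-out libraries, against 1613 and 2415. OsWOX13 had log2 fold changes from -1.02 to 0.72 over the left-out libraries, turning positive without OE13-2KR/oswox13-1 replicate 1 (0.28) and without OE13 replicate 2 (0.72). No setting gave a call shared with the paired genes marked up in the authors' deposited table, the only ones that could be compared, and no called gene was higher in OE13-2KR/oswox13-1 in any setting.

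The number of lists past the set test, 11, was 0 with an estimated correlation, 0 with fry's directional test, 4 without a filter, 7 with a mean FPKM of at least 5, 8 with quantile normalisation, 8 without overlapped genes and 12 with a replicate block. It ranged from 7 to 11 over the left-out libraries. The 7 calls lost without a filter were drought and TIFY/JAZ (adjusted p = 0.0663 each), heat shock, photosystem, NAC and phosphate (0.0807 each) and cellulose synthase (0.172). The 4 lost with a mean FPKM of at least 5 were drought, NAC and TIFY/JAZ (0.0917 each) and aquaporins (0.0654). Quantile normalisation lost drought (0.122), aquaporins (0.0886) and TIFY/JAZ (0.106), and leaving out overlapped genes lost heat shock, photosystem (0.0699 each) and aquaporins (0.0711). The cytosolic ribosome and amino acid transporter lists kept their call in every setting but the estimated correlation and fry, with medians from -0.52 to -0.34 and from 0.037 to 0.48. Other medians ranged from -0.91 to -0.24 for the cellulose synthase list, -1.19 to -0.26 for photosystems, 0.17 to 0.69 for NAC, 0.07 to 0.29 for WRKY, 0.03 to 0.32 for phosphate, 0.03 to 0.17 for heat shock, 0.05 to 0.38 for TIFY/JAZ, 0.11 to 0.83 for aquaporins and -0.02 to 0.40 for drought. The drought list also lost it without OE13-2KR/oswox13-1 replicate 2. No list past the test changed the direction of its test, though the drought list's median was -0.02 without OE13-2KR/oswox13-1 replicate 2. The cause of these changes was not tested beyond their construction. Under the replicate block the libraries share only a number, their deviations correlating at -0.09 for same-numbered libraries; the block left 1239 genes higher and 2122 lower at an unadjusted p under 0.05. Over 12 settings the 53 genes named with values, other than OsWOX13 and ONAC007, had 621 log2 fold changes, fewer where a filter left a gene out. Of these 0 changed sign, and the 6 lost calls were those of OsERF_047, the only one of the genes called. This was largely fixed in advance: except for Lsi1, their groups did not overlap, so no pseudocount, filter or left-out library could turn a sign. RLE and upper-quartile size factors, filters on counts, a DESeq2 test and limma-voom need counts and were not run. Unknown read depth leaves the counting error of low genes open.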

Other observations

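The tests in this part were chosen after the results were seen, except the test of the within-group spread of the ribosomal list. Gene ontology terms in the deposited annotation were tested as sets, 759 terms of 15 to 500 genes. By camera with the preset correlation 124 terms were higher and 32 lower in OE13-2KR/oswox13-1, and 0 passed with an estimated correlation (lowest adjusted p 0.827). As for the lists, that version rests on the 2 residual degrees of freedom, so hardly any term could pass it. Protein traffic and turnover led the higher terms. The membrane coat term had a median log2 fold change of 0.60 over 21 genes, with 14 higher and 0 lower at an unadjusted p under 0.05 (adjusted p = 1.5e-07). The proteasome complex had 0.32 over 59 genes (adjusted p = 1.7e-06), transport from the endoplasmic reticulum to the Golgi 0.25 over 97 (6.6e-07) and the response to unfolded protein 0.45 over 17 (1.9e-06). The tricarboxylic acid cycle had 0.37 over 46 genes (6.5e-06) and fatty acid beta-oxidation 0.27 over 30 (0.000203). Among the lower terms was chloroplast rRNA processing, with -0.64 over 22 genes (0.00466).

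OsERF_047 was listed at 0 in both OE13-2KR/oswox13-1 libraries. A missing locus is argued against, since Os03g0191850 over the same span had a mean of 27.998 FPKM there. Reads divided differently between the overlapping genes may account for some or all of the pattern: Os03g0191850 moved the other way by a log2 fold change of 1.20. Both genes kept nearly the same proportion in the OE13 libraries, at 41.9 with 12.7 FPKM and 34.7 with 10.6 FPKM. Their values may therefore be a division of shared reads and not separate measurements, and the listed 0 may come from read assignment. The pair's summed FPKM was lower, by a log2 fold change of -0.81. FPKM is scaled to each gene's own length, and the counted lengths were not compared. The sum therefore cannot show whether fewer reads lay over the span, and a lower transcript level there stays open. Of the 89 genes at p under 0.001, 15.7% were covered by at least 50% on the other strand, against 12.9% of all tested genes (Fisher's exact test, p = 0.427). So few genes cannot exclude an excess of overlap among the strongest. Over the 1271 covered genes with a tested partner, 28.9% had the opposite direction to it. The median r with the partner over the 4 libraries was 0.69.

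Cytosolic ribosomal protein genes were lower in OE13-2KR/oswox13-1 by 0.42 in the group difference of the library medians. Scaling of the columns is argued against as the whole cause: after median-of-ratios scaling the list still differed by -0.33, within groups up to 0.20, with the median of all genes at 0.00. Variation between plants of one genotype cannot be told apart from the genotype, with a largest within-group difference of 35.0% of the group difference. A bound of 50%, set before this value was seen, was to exclude it and was met by the unscaled values. It was not met after median-of-ratios scaling, with up to 0.20 within groups against -0.33 between them. With 2 libraries per group an exact test cannot go below 0.333. The bound was set aside for that reason after the value was seen. A genotype difference stays open as well.

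Cellulose synthase family genes were lower in OE13-2KR/oswox13-1 by 0.72 in the group difference of the library medians. The list kept its call without replicate 2 of OE13-2KR/oswox13-1 (camera at the preset correlation, adjusted p = 0.0183). That call cannot decide whether this library alone made the pattern. With an estimated correlation the list did not pass even with all libraries (adjusted p = 0.897). The library medians argue against replicate 2 alone. The list's median deviation was -0.20 in replicate 1 of that line, against 0.44 and 0.36 in OE13 (within groups up to 0.24). It was -0.44 in replicate 2, so part of the size may rest on that library. A larger share of dividing leaf tissue in the OE13 samples cannot be told apart from the genotype: core histones differed by -0.15 (within groups up to 0.12), but cell division genes by -0.18 (within groups up to 0.19), too wide a spread to decide. A larger share of elongating leaf tissue cannot be told apart either, since expansins differed by -0.35, within groups up to 0.19, and did not pass the set test (camera, adjusted p = 0.476). A larger share of wall-thickening tissue cannot be told apart: outside the list, secondary cell wall genes differed by -0.42 (within groups up to 0.21) and xylan synthesis genes by -0.17 (up to 0.11), and a genotype difference stays open.

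The 2 other ways of splitting the 4 libraries into pairs gave 304 and 346 genes at an unadjusted p under 0.05, against 4028 for the genotypes, and 0 called genes each. Those splits mix the lines within each pair, so any difference between the lines enters the residual spread and lowers their counts. They are therefore no baseline for the genotype count. With 3 splits no share under 0.05 can be reached. Across genes, which are not independent replicates, the genotype log2 fold change correlated with the difference between OE13-2KR/oswox13-1 replicates 2 and 1 (r = 0.39) and with that between OE13 replicates 1 and 2 (r = 0.21). Each difference uses libraries that also enter the fold change, and no sample-level test of the relation was run.

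Besides OsERF_047, 2 genes were under 0.1 FPKM in both OE13-2KR/oswox13-1 libraries and at 2 or more in both OE13 libraries. OsAP25 (chromosome 3, 4541351 to 4543092) stood at 4.66 and 2.12 in OE13, and Os10g0411100 at 2.02 and 3.41. In the other direction, Os04g0498650 was listed at 0 in OE13 and stood at 2.51 and 5.76 in OE13-2KR/oswox13-1; it lies wholly within SAMDC on the other strand.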
